A study of Mus musculus with 6 samples.

How the data were processed

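RNA sequencing measured transcripts in 6 libraries of sorted mouse bone marrow HSCs, 3 from Ramp1+/+ and 3 from Ramp1 mutant mice, grouped by genotype as the labels give it. The submitters' processing notes name CASAVA, STAR, HTSeq 0.6.1, DESeq2 and the genome build mm10, with no role or order for them. The annotation release is not given in the sources used here, nor is whether counting used strand, so overlapping genes and near-identical copies may share reads.

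A table from the authors holds raw read counts per gene, deposited with the authors' size-factor-normalized values (a signal unit, not used here), FPKM, gene coordinates, log2 fold changes and p-values. A deposited FPKM table covers 35275 genes, with values scaled by gene length and by the counted reads of the library; per the file headers both tables name the libraries. In the authors' deposited log2 fold changes a negative value means lower in mutant cells, and 16021 of their genes have an adjusted p-value. The count table holds 18368 genes, which are those with reads in mutant replicate 1 or 2: 0 genes in it lack reads in both, and 0 of the genes outside it have any there. It therefore leaves out 2054 genes with FPKM above 0 elsewhere, 14853 genes being at 0 in every library. For 1996 of the 2054, whole reads were estimated from the FPKM steps (tolerance 0.002 reads plus the rounding of the FPKM values) and added in an alternative. Their sums were 106.9% to 108.4% of the reads outside the count table in the 4 libraries that have any, so some of these estimates are too high. Of the gene names, 27 had been turned into dates in the FPKM table, and 22 names that differed were replaced by those of the count table.

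The counts summed to between 22796771 and 26734561 per library. edgeR 4.0.16 in R 4.3.3 was run on the deposited counts with TMM scaling, filterByExpr and the quasi-likelihood F test, which left 14443 genes. A Benjamini-Hochberg adjusted p under 0.05 was the threshold, two-sided; the standard error is the log2 fold change divided by the square root of F. Gene lists were tested with camera on log2 CPM (prior count 2, preset correlation 0.01) where at least 5 members were tested, with an adjustment over 30 lists. camera with an estimated correlation and fry were run beside it. With an estimated correlation camera uses the few residual degrees of freedom of 6 libraries and has little power. 2 of 32 lists, the CGRP receptor and the sex-linked list, had too few members for a set test. Of 767 list symbols, 5 had no match and 7 were matched through the gene identifier. Genes near Ramp1 were those starting within 10 Mb, by the coordinates in the authors' table, compared with others by Fisher's exact test and camera. Lengths and GC content for a bias check came from a GENCODE annotation of the same build.

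The samples, tests, lists, named-gene rule and first set of alternatives were fixed before the data were examined. The rule named Ramp1, Calcrl, Ramp2, Ramp3 and Calca; genes past the threshold with non-overlapping groups and at least 2 FPKM, up to 12 per direction, or, with fewer than 5, a list filled to 10 by the smallest unadjusted p; up to 4 members of each list described, with at least 1 FPKM; and Xist, Ddx3y, Uty, Kdm5d and Eif2s3y. Names of predicted or clone-based genes were left out of the second part. Some genes that the rule names are not reported or drawn here.

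The gene test was checked on simulated counts for 14443 genes with the real means, library sizes and dispersions, for mutant minus wild type. With 50 genes changed at each fold, edgeR recovered 20% of genes changed 1.5-fold, 52% at 2-fold, 72% at 4-fold and 84% at 8-fold. Of its calls, 9.52% were unchanged genes. DESeq2 1.42.0 recovered 30%, 58%, 80% and 88%, and 26.4% of its calls were unchanged genes. An adjusted threshold loosens as more genes change, so these shares may be too high for the real libraries, which gave fewer calls. Without any simulated change edgeR called 0 genes, camera 0 lists and the window scan 0 windows. The simulated genes varied independently of each other, so the 0 lists and 0 windows do not show how these tests behave with correlated genes. Other splits of the real libraries gave up to 14 lists and up to 13 windows outside chromosome 1. No pair of libraries agreed within sampling noise, as 1 library deposited more than once would; this does not show that they came from separate animals.

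Alternatives were other scalings, filters, thresholds and windows, DESeq2, limma 3.58.1 on log2 FPKM, each library left out in turn, and the replicate number as a block. The pseudocounts and FPKM scalings were meant for FPKM as the main unit; they were run as added settings of the limma fit. Other added settings, chosen after seeing the data, were a robust fit, limma-voom, the presence of Y-linked reads as a covariate, leaving out both libraries with such reads, and the recovered reads. The count of genes near Ramp1 under settings other than the window size was also added then.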

Results

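RNA was sequenced from about 2000 sorted haematopoietic stem cells (HSCs) of adult mouse bone marrow per library. HSCs are the rare marrow cells that sustain all blood lineages. The 6 libraries fell into 3 from Ramp1+/+ mice, called wild type here, and 3 from mice carrying a Ramp1 mutation. Ramp1 encodes the accessory protein that, with the receptor Calcrl, forms the receptor for the neuropeptide CGRP. The series title places the comparison in a study of pain-sensing nerves and stem cell mobilization, so the question addressed is which transcripts differ in HSCs of mice with this mutation. Each library held between 22796771 and 26734561 reads counted in genes. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries only.

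The targeted gene separated the groups in every library. Ramp1 (ENSMUSG00000034353, protein-coding, mm10 chromosome 1, 91179822 to 91225196) had 90.2 ± 1.7 FPKM in wild-type HSCs and 2.51 ± 1.1 FPKM in mutant HSCs (SD, n = 3 each). Its level in the mutant libraries was 2.78% of that in wild type, a log2 fold change of -5.17 (SE 0.31; edgeR quasi-likelihood test, adjusted p = 0.00146). An exact two-sided permutation test of the 3 against 3 values gave p = 0.1, the smallest this design allows. The labels do not say which part of the gene the allele removes, and the remaining mutant reads were not assigned to exons here. Its partner Calcrl was abundant in both groups, at 50.3 ± 3.18 FPKM in wild type and 60.8 ± 13 FPKM in mutant cells, and did not pass the test (log2 fold change 0.27, SE 0.15). Ramp2, which pairs with Calcrl to form an adrenomedullin receptor, was low at 3.79 ± 1.22 and 4.24 ± 0.934 FPKM (log2 fold change 0.16, SE 0.33). Crcp, another member of the list of CGRP receptor and ligand genes, had a log2 fold change of 0.20 (SE 0.14). Ramp3 and Calca, the latter encoding CGRP itself, had values only in the FPKM table, with wild-type means of 0.0422 and 0.165 FPKM and 0 in all mutant libraries. Both were also at 0 in wild-type replicate 1. Any gene outside the count table is at 0 in mutant replicates 1 and 2, so these values do not separate the groups. With 4 tested members, the CGRP receptor list had too few for a set test, and Ramp1 was its only member past the threshold, also when adjusted over the list alone.

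**Figure D1:**
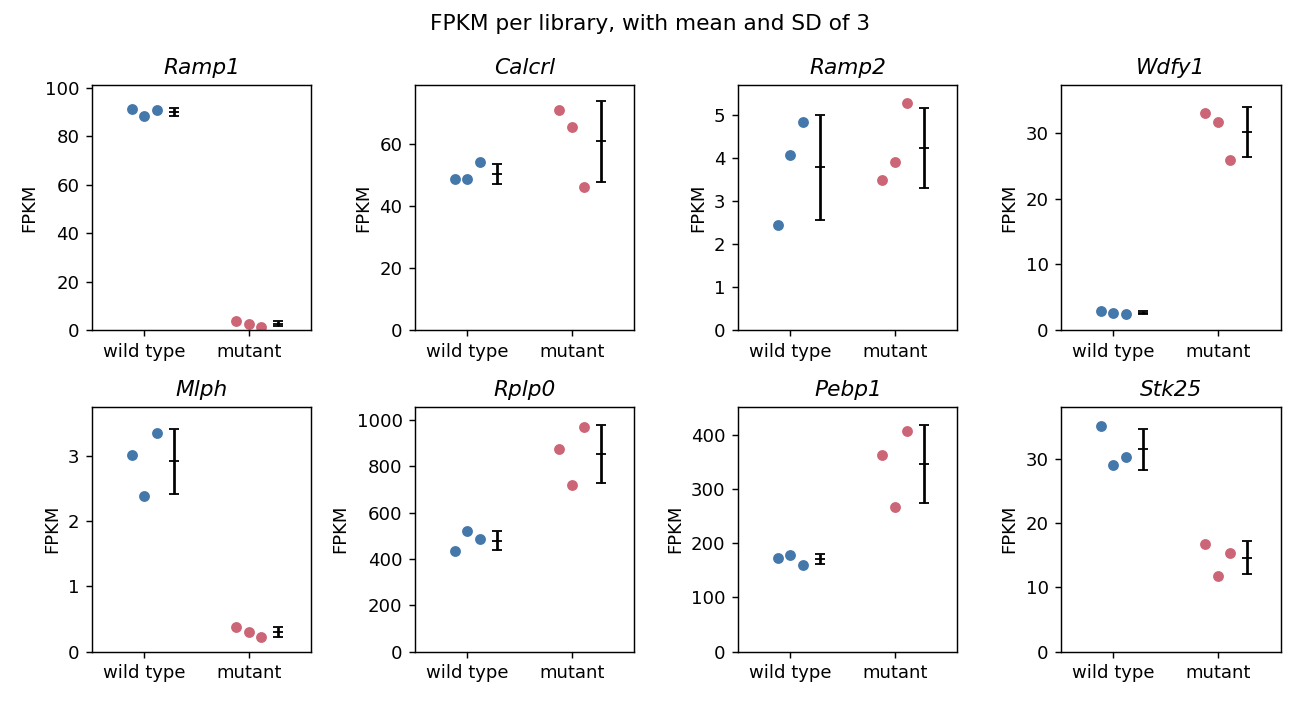
FPKM of 8 genes in each library, with wild type in blue, mutant in red, and the mean and SD of 3 libraries as a black bar; all axes start at 0. Ramp1 fell from 90.2 to 2.51 FPKM, Wdfy1 rose from 2.65 to 30.2 FPKM, and the Calcrl and Ramp2 values of the groups overlapped.

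Apart from Ramp1, 2 of the 14443 genes tested passed an adjusted p of 0.05. Wdfy1 (ENSMUSG00000073643, chromosome 1, 79702262 to 79776143), which encodes a phosphoinositide-binding endosomal protein, rose from 2.65 ± 0.238 to 30.2 ± 3.81 FPKM (SD, n = 3 each; log2 fold change 3.51, SE 0.14; edgeR adjusted p = 1.33e-04). Mlph (ENSMUSG00000026303, chromosome 1, 90915085 to 90951142), which encodes the melanosome transport protein melanophilin, fell from 2.92 ± 0.499 to 0.304 ± 0.0782 FPKM (log2 fold change -3.26, SE 0.30; edgeR adjusted p = 0.0244). In all, 1 gene was higher and 2 were lower in mutant HSCs. At an unadjusted p under 0.05 there were 330 higher and 246 lower genes, 576 together. Of all genes tested, 10.3% had 3 mutant libraries entirely above or below the 3 wild-type libraries, where chance gives 10%. DESeq2 on the same counts called 21 higher and 23 lower genes. Ramp1 and Wdfy1 passed without each of the 6 libraries in turn, while Mlph lost its call in each of these 6 cases: its adjusted p was 0.193, 0.0587 and 0.123 without wild-type replicates 1, 2 and 3 and 0.0826, 0.0600 and 0.0911 without mutant replicates 1, 2 and 3. Its log2 fold change stayed between -3.43 and -3.09 in these cases, each with 1 library fewer. There were 2 higher genes without wild-type replicate 2 or 3 or mutant replicate 2 and 1 otherwise, and 4 lower genes without mutant replicate 2 and 1 otherwise.

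The genes next in rank did not pass the threshold, and their values are given as such. Among those with higher values in all mutant libraries, Pebp1, a Raf kinase inhibitor, had 170 ± 9.61 FPKM in wild type and 346 ± 71.6 FPKM in mutant cells (log2 fold change 1.02, SE 0.15; edgeR adjusted p = 0.297). Rbpj, the DNA-binding effector of Notch signalling, had a log2 fold change of 0.86 (SE 0.17). The ribosomal stalk gene Rplp0 had 0.83 (SE 0.13), the sulfotransferase gene Sult1a1 0.65 (SE 0.11) and the septin gene Sept2 0.52 (SE 0.08). Rpl35, Rps29 and Rps25, genes of ribosomal proteins, had 0.62, 0.48 and 0.44. Among those with lower values, Larp1, which binds mRNAs of the translation machinery, had a log2 fold change of -1.40 (SE 0.27) and the kinase gene Stk25 -1.10 (SE 0.14). Lonrf1 had -1.0, Lancl1 -0.90, Acadl -0.89 and Snx25 -0.85, while D2hgdh had -0.74. Acadl encodes a mitochondrial acyl-CoA dehydrogenase and D2hgdh a dehydrogenase of D-2-hydroxyglutarate. The edgeR adjusted p-values of these genes lay between 0.179 and 0.755. Several share a chromosome with Ramp1: Sept2, Stk25, Lancl1, Acadl and D2hgdh lie on chromosome 1. Pebp1, Rplp0 and Rbpj lie on chromosome 5, and Lonrf1 and Snx25 on chromosome 8. Larp1, Sult1a1, Rpl35, Rps29 and Rps25 lie on other chromosomes.

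Both genes called besides Ramp1 lie on chromosome 1, as does Ramp1. Mlph starts 0.26 Mb before Ramp1 and Wdfy1 11.48 Mb before it. Within 10 Mb on each side of Ramp1, 1 of 112 other tested genes passed the adjusted threshold, against 1 of 14330 elsewhere (two-sided Fisher's exact test, p = 0.0155). The count rests on Mlph. It was 0 without wild-type replicate 1 or 2 or mutant replicate 1, 2 or 3, and 1 without wild-type replicate 3, where Pam passed (adjusted p = 0.00159) and Mlph did not. At an unadjusted p under 0.01 the window held 11 of 112 genes and the rest of the genome 108 of 14330 (odds ratio 14.3, Fisher's exact p = 1.94e-09). Fisher's test treats neighbouring genes as independent, so this p may be too small. When the p-values were moved around the genome in gene order, a share of 0.00400 of 10000 moves put as many into the window. The highest count in these moves was 12. Moves by few genes keep part of the same region in the window and were not left out, so the highest counts may come from there. The 11 genes went both ways, 6 higher and 5 lower, in a table that leaves out genes without reads in mutant replicates 1 and 2. With recovered reads for those there were 13 of 114, 6 higher and 7 lower, with Glrp1 and Rbm44 added to the lower ones. A camera test of the 112 genes as a set did not pass. Stk25, D2hgdh and Ugt1a7c were among those with lower values and Sept2 and Pam, an enzyme of peptide amidation, among those with higher values. Pam had 3591 to 3903 reads in the mutant libraries, while the wild-type libraries held 554, 510 and 2039. Glrp1, Rbm44, Pam, Ugt1a7c and the 3 transcripts named next lie outside the rule for named genes and were chosen after their values were seen. Gm9994 (93918311 to 93942650), RP24-171A4.1 (93975353 to 93985816) and RP23-397C14.2 (93906244 to 93916768) had 0 reads in the wild-type libraries and 169, 69 and 44 reads over the mutant libraries. Against a floor of 3 reads over the wild-type group they were at least 55.9-fold, 22.8-fold and 14.5-fold higher, with counting error only behind these bounds.

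**Figure D2:**
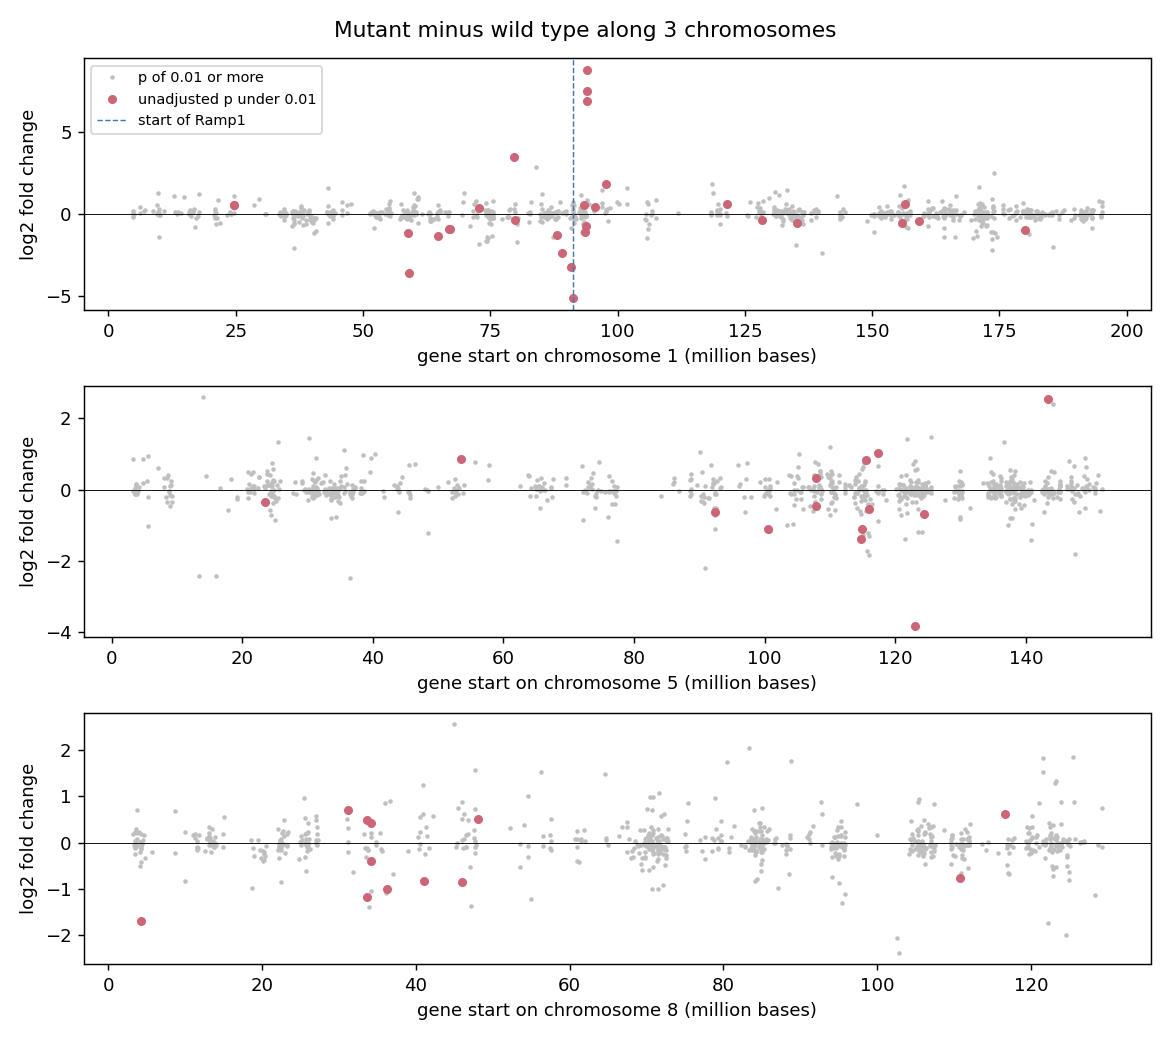
Log2 fold change, mutant minus wild type, of tested genes by their start on chromosomes 1, 5 and 8 in Mb; red points have an unadjusted p under 0.01 and the dashed line marks Ramp1. Near Ramp1 red points lie on both sides of 0, and the 3 highest points are transcripts with 0 wild-type reads, whose fitted values depend on the prior count.

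The authors' deposited table lists 37 genes past an adjusted p of 0.05, with 16 higher and 21 lower in the mutant. All 37 had the same direction in the edgeR fit, all had an unadjusted p under 0.01 there, and 3 passed its adjusted threshold. Of these 37 genes in the authors' deposited table, 12 lie on chromosome 1, 8 on chromosome 5 and 5 on chromosome 8. Chromosome 1 held 32.4% of these calls and 6.3% of all genes in the count table. Such shares were not computed for chromosomes 5 and 8. The table's higher genes include 6 of ribosomal proteins, with Rplp0 counted among them. DESeq2 run here called 44 genes, which included all 37. Both fits used the authors' deposited read counts, so the shared directions and calls are not independent support.

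Lists of ribosomal proteins, mitochondrially encoded genes and nuclear oxidative phosphorylation genes were slightly higher as groups in the preset test. Of 94 tested genes of ribosomal proteins, 86 had higher and 8 lower values in mutant HSCs, with a median log2 fold change of 0.15. The list rose by camera with a preset correlation (adjusted p = 3.82e-12), but not with an estimated correlation (adjusted p = 0.857 with an estimated correlation). None of its members passed over all genes tested and 7 did when adjusted over the list alone, including Rps25 (532 ± 15.8 against 720 ± 39 FPKM), Rps29 and Rpl41 (log2 fold change 0.36). All 13 mitochondrially encoded genes had higher values, with a median log2 fold change of 0.29 (camera adjusted p = 4.94e-05; adjusted p = 0.857 with an estimated correlation). Examples are mt-Co3 at 0.47 (SE 0.15) and mt-Co2 at 0.39 (SE 0.13), subunits of cytochrome c oxidase. Of 73 nuclear genes of oxidative phosphorylation, 53 had higher values, by a median of 0.09 (camera adjusted p = 0.00372; adjusted p = 0.871 with an estimated correlation), with Atp5l at 0.37 and Uqcrh at 0.30. This list lost its call without wild-type replicate 3 (adjusted p = 0.609) and without mutant replicate 3 (0.850). The glycolysis list, with 14 of 21 members lower, did not pass (camera adjusted p = 0.390).

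Cell cycle genes were lower as groups in the preset test. Of 56 tested G2/M genes, 50 had lower values, with a median log2 fold change of -0.19 (camera adjusted p = 8.93e-05; adjusted p = 0.857 with an estimated correlation). Ttk, a spindle checkpoint kinase, had -0.57 (SE 0.23), and Gas2l3 went the other way at 0.33 (SE 0.13). Of 47 S phase genes, 43 had lower values, by a median of -0.15 (camera adjusted p = 0.00372; adjusted p = 0.871 with an estimated correlation), with Mcm6 at -0.31 (SE 0.20). Of 28 replication-dependent histone genes, 21 had lower values (median -0.27; camera adjusted p = 0.00591; adjusted p = 0.857 with an estimated correlation). No member of these 3 lists passed, also when adjusted over the list alone. Without mutant replicate 2 the G2/M list had an adjusted p of 0.420 and the S phase list 0.396; the S phase list had 0.226 without wild-type replicate 2 and 0.736 without mutant replicate 1. With no filter on low counts the histone list had 0.103. The mutant libraries differed among themselves by more than the groups did: G2/M genes lay at a median of -0.19 and -0.47 from the mean of all libraries in mutant replicates 1 and 2 but at 0.34 in mutant replicate 3.

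Stem cell genes showed small differences. In the long-term HSC signature 31 of 41 genes had higher values, by a median of 0.10 (camera adjusted p = 0.0228; adjusted p = 0.857 with an estimated correlation). The call was lost without wild-type replicate 1 (adjusted p = 0.0991) or 2 (0.218), without mutant replicate 1 (0.354) or 2 (0.154), and with no filter on low counts (0.103). Sult1a1 (35.6 ± 2.27 against 55.6 ± 1.81 FPKM) passed when adjusted over the list alone and not over all genes, and Tcf15, a transcription factor of quiescent HSCs, had a log2 fold change of 0.50 (SE 0.18). The lists of HSC retention, adhesion and mobilization genes (22 of 35 higher; camera adjusted p = 0.367), quiescence and FoxO genes (19 of 27 higher; 0.261) and multipotent progenitor and lymphoid-primed genes (10 of 14 higher; 0.937) did not pass. In the mobilization list Itgb3, the integrin beta 3 subunit, had 14.2 ± 1.52 FPKM in wild type and 26.3 ± 8.7 FPKM in mutant cells (log2 fold change 0.90, SE 0.25), and no member passed over the list alone.

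Signalling lists tied to the receptor were examined next, since CGRP receptors raise cyclic AMP through Gs. Genes of Gs, adenylyl cyclases and protein kinase A did not pass (18 of 26 higher; camera adjusted p = 0.937), and neither did other neuropeptide and adrenergic receptors (3 of 8 higher; 0.690). The cAMP/CREB response genes had 16 of 25 members higher (camera adjusted p = 0.133); this list passed without wild-type replicate 3 (0.0302) and without mutant replicate 1 (0.00718). With all libraries it had an adjusted p of 0.857 with an estimated correlation. Immediate early and stress genes, which share members with that list, rose in the preset test, with 19 of 23 higher and a median log2 fold change of 0.54 (camera adjusted p = 0.00609; adjusted p = 0.857 with an estimated correlation). Fos had 5.58 ± 3.52 FPKM in wild type and 26.9 ± 22.5 FPKM in mutant cells, and Junb 26.9 ± 3.46 and 45.1 ± 18. Unfolded protein response and heat shock genes had 25 of 32 members higher (median 0.13; camera adjusted p = 0.0103; adjusted p = 0.857 with an estimated correlation), with Dnajc3, a chaperone of the endoplasmic reticulum, at 0.41 (SE 0.12). The immediate early list lost its call without wild-type replicate 1 (adjusted p = 0.113), mutant replicate 2 (0.183) or mutant replicate 3 (0.320). The unfolded protein list lost its call without wild-type replicates 1 (0.0614) or 3 (0.338) and mutant replicates 2 (0.154) or 3 (0.617), and with no filter on low counts (0.0530).

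**Figure D3:**
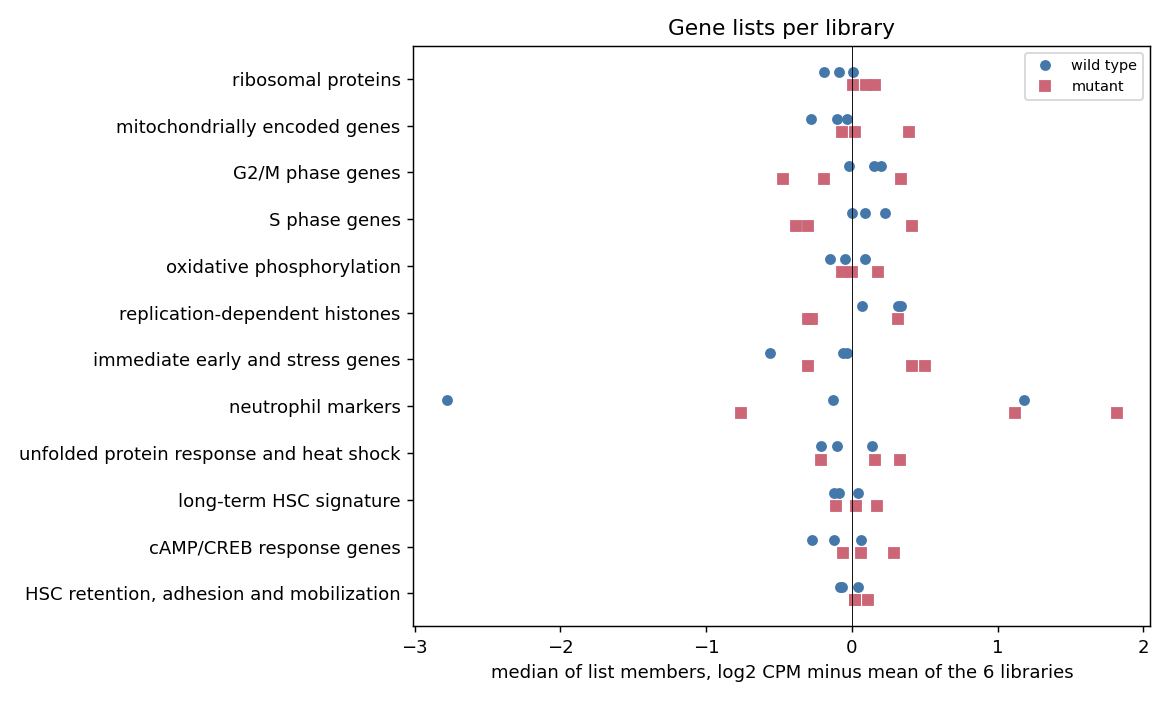
Median over list members of log2 CPM minus the mean of the 6 libraries, for 12 gene lists; each blue circle is a wild-type library and each red square a mutant library. Neutrophil markers range from -2.78 to 1.82, more widely than the other lists drawn.

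Neutrophil markers varied widely between libraries of the same group. All 17 tested neutrophil markers had higher values in mutant libraries (median log2 fold change 0.70; camera adjusted p = 0.00913; adjusted p = 0.857 with an estimated correlation), but S100a8 had 133 ± 141 FPKM in wild type and 292 ± 193 FPKM in mutant cells. The library medians were -2.78, -0.13 and 1.18 in wild type and -0.76, 1.12 and 1.82 in mutant. The list had an adjusted p of 0.856 without wild-type replicate 1, 0.166 without mutant replicate 2 and 0.354 without mutant replicate 3. Replicate 1 was the lowest of its group for neutrophil markers and for immediate early genes, and in both groups replicate 1 was also the only library with Y-linked reads, 6527 in wild type and 6137 in mutant against at most 2 elsewhere. Xist had 10 and 5 reads in those libraries and 1456 to 3540 in the others. This is the pattern of male cells in replicate 1 and of female cells in replicates 2 and 3 of both groups. The main fit had no term for sex. Lists of markers of erythroid (camera adjusted p = 0.297), megakaryocyte and platelet (0.966), granulocyte-monocyte progenitor (0.390), macrophage and monocyte (0.937) and B and plasma cells (0.0656) did not pass. Neither did those of T and NK cells (0.755), dendritic cells and MHC class II (0.773), mast cells, basophils and eosinophils (0.390) or endothelial and stromal cells (0.308). Single members passed when adjusted over the list alone, Slc4a1 among erythroid genes and Plac8 among granulocyte-monocyte progenitor genes; Plac8 had 61.6 ± 17.3 FPKM in wild type and 28.4 ± 6.53 FPKM in mutant cells. The remaining lists, cholesterol biosynthesis (0.279), interferon response (0.590), NF-kB and inflammatory genes (0.773) and p53 targets (0.807), did not pass either. Some of these lists passed with 1 library left out: erythroid markers without wild-type replicate 2 (0.00933), B and plasma cell markers without wild-type replicate 2 (0.00933) or mutant replicate 1 (0.0160), macrophage markers without mutant replicate 1 (0.0214, then toward higher values), cholesterol biosynthesis without wild-type replicate 1 (0.0389) or mutant replicate 3 (0.0241) and interferon response without wild-type replicate 3 (0.00105) or mutant replicate 3 (0.0152). T and NK cell markers passed with the stricter filter (0.0495). With all libraries and an estimated correlation the adjusted p of these 6 lists was 0.857 for B and plasma cells, 0.871 for erythroid, T and NK cell and cholesterol genes, 0.942 for interferon response and 0.981 for macrophages.

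Of 30 lists tested, 10 passed with the preset correlation and 0 with an estimated correlation or with fry. Correlation between genes does not account for this alone. The histone list had an estimated correlation of 0.017, near the preset 0.01, yet its unadjusted camera p went from 0.00118 to 0.0389. With an estimate, camera also rests on the few residual degrees of freedom of 6 libraries, so hardly any list could pass. Without mutant replicate 2 the number was 4, and with no filter on low counts it was 7. Of the 10, those of ribosomal proteins, mitochondrially encoded genes and histones passed without each of the 6 libraries in turn, and the others lost their call without at least 1 library.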

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

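The tests of mapping loss and of neutrophil RNA and the fits with recovered reads were chosen after the result was seen. The search for genes with values in 1 group alone was not among the tests fixed beforehand. The other tests of explanations in this part were written down before the result was seen. Among genes that the count table leaves out, 42 had FPKM above 0 in all wild-type libraries and 0 in all mutant libraries, and 4 of these, at 0.5 FPKM or more in each wild-type library, are given as a signal in data outside the main comparison. The opposite pattern held for 40 genes among all those with FPKM values, 3 of them at 0.5 FPKM or more in each mutant library. Rbm44 (chromosome 1, 91145089 to 91170795), next to Ramp1, had a wild-type mean of 2.10 FPKM with about 414, 65 and 124 recovered reads, and Glrp1 (chromosome 1, 88499871 to 88510066) had 1.78 FPKM with 60, 111 and 85. Gm14087 had 2.19 FPKM and Gm15197 (chromosome 10, 42330786 to 42331263) 0.627 FPKM. With recovered reads in the edgeR fit none of the genes outside the count table passed, Glrp1 at an adjusted p of 0.152 and Rbm44 at 0.367.

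Changed genes gathered near Ramp1 on chromosome 1. Of the 11 genes with p under 0.01, 6 were higher in mutant libraries, 3 of them with reads in mutant libraries alone, and 5 were lower. The count table leaves out genes without reads in mutant replicates 1 and 2; with recovered reads in the fit Glrp1 and Rbm44 join the lower ones, which gives 13 genes, 6 higher and 7 lower. Reads of a differing strain lost in mapping stay open for both directions, since the labels do not say which libraries carry sequence that differs from the reference. Neighbouring genes varying together were tested by moving the p-values around the genome as a ring, and a share of 0.00400 of 10000 moves put as many genes into the window. The real split gave 11 such genes and the highest of the other splits 3; it was 1 of 10 splits with as many, and 10 splits are too few for a share under 0.05. Flanking DNA carried with the mutant allele, a regulatory effect of the allele on its neighbours and an effect of the lower Ramp1 level remain open too, since strain variants were not analysed here.

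The higher values of ribosomal protein genes were weighed against 3 technical explanations. After a trend with gene length, GC content or expression level was removed the median stayed at 0.12, against 0.15 before. Under 2 other scalings between libraries the lowest median was 0.14, and leaving out 1 library gave 0.12 at the lowest and 0.21 at the highest. Among the splits of the libraries 2 of 10 gave a median as far from 0 as the real 0.15, the highest other being 0.18, and 10 splits are too few to judge chance. Genotype remains open beside differences between animals or sorts that the labels do not record.

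The neutrophil markers may reflect neutrophil RNA carried into the sorted cells, which these values cannot decide. Of 17 markers 17 were higher, S100a8 at a log2 fold change of 1.15 and S100a9 at 1.03. This restates the pattern and would follow from any cause that raises the whole list. The sort for HSCs would be meant to remove neutrophils. The median was 1.03 with the presence of Y-linked reads as a term of the fit and 0.70 without it. In each group 1 of 3 libraries held such reads, so a difference of equal size in both groups cannot produce the higher mutant values. A difference of unequal size was not tested by that term. Leaving out 1 library moved the median between 0.25 and 1.96. Of 10 splits 6 gave a median as far from 0 as 0.70, the highest other 2.41, so the libraries differed in this respect along lines other than genotype; 10 splits are too few for a share under 0.05.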

How the results depend on the processing

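The limma settings on FPKM other than log2(FPKM + 1), the robust fit, limma-voom, the Y-linked covariate, leaving out both libraries with Y-linked reads, the recovered reads, the block with an estimated correlation, the wider threshold for the authors' table and, for the window near Ramp1, all settings but its size were chosen after seeing the data. Ramp1 kept its direction and stayed past the threshold under every alternative run, at -5.47 to -4.75, and at -5.47 to -4.88 with 1 library left out. The cause of the changes below was not tested. The 1 higher gene became 2 with no filter, the stricter filter, a robust fit, an adjusted p under 0.1 and limma on FPKM + 1, FPKM + 0.1, FPKM + 0.5, quantile-normalized FPKM, TPM and a mean FPKM of at least 5; DESeq2 gave 21. The 2 lower genes became 1 in all 7 limma fits on FPKM or TPM, with limma-voom, the Y-linked covariate and without both libraries with Y-linked reads; DESeq2 gave 23. In those same fits the 1 gene near Ramp1 became 0; DESeq2 gave 7 and a window of 20 Mb gave 2. With 1 library left out the ranges were 1 to 2 higher, 1 to 4 lower and 0 to 1 near Ramp1; 4 lower came without mutant replicate 2 and 1 near Ramp1 without wild-type replicate 3. The 10 gene lists became 0 with an estimated correlation, 0 with fry, and 4 to 11 with 1 library left out, 4 being without mutant replicate 2. The authors' deposited table holds 57 genes at an adjusted p under 0.1, against 37.

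With the replicate number as a block there was 1 lower gene and 0 near Ramp1, 12 lists passed against 10, and 0 passed with the block and an estimated correlation. The numbers did not pair the samples in general: deviations of same-numbered libraries correlated at 0.14, 0 and -0.09. Of 6 libraries, 2 correlated best with their own number. Replicate 1 did match between the groups in being the only library with Y-linked reads. On the first principal component of log2 CPM (26.1% of the variance) replicate 1 lay at -36.3 in wild type and -39.7 in mutant. The other libraries lay between 3.5 and 55.4.

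Directions reversed for genes that had not passed. Cd247 had -0.02 with the block, -0.03 on FPKM + 0.1, 0 on TPM, -0.05 with limma-voom and -0.05 without both libraries with Y-linked reads. With 1 library left out the log2 fold changes ran from -0.07 to 0.36 for Ramp2, -0.73 to 0.96 for Xist, -0.31 to 0.27 for Sstr2, -0.04 to 1.34 for Cdkn1a, -0.18 to 0.54 for Cd247, 0 to 0.24 for H2-DMb1, -0.04 to 0.74 for H2-Aa, -0.23 to 0.49 for Il4 and -0.63 to 0.28 for Cpa3. Lists that had not passed also turned, here with their adjusted p. With no filter these were Gs and PKA components (0.826), megakaryocyte markers (0.817) and T and NK markers (0.403); with the stricter filter other neuropeptide receptors (0.888); with the block megakaryocyte markers (0.987, and 0.994 with an estimated correlation). Without both libraries with Y-linked reads they were other neuropeptide receptors, Gs and PKA components, interferon response and megakaryocyte markers (0.672 each), retention genes (0.743), mast cell markers (0.531) and macrophage markers, which then passed (0.00479). With 1 library left out the adjusted p ran from 0.287 to 0.931 for other neuropeptide receptors, 0.698 to 0.967 for Gs and PKA components, 0.406 to 0.904 for multipotent progenitor genes, 0.0241 to 0.887 for cholesterol biosynthesis, 0.00105 to 0.815 for interferon response, 0.584 to 0.967 for p53 targets, 0.13 to 0.836 for granulocyte-monocyte progenitors, 0.0214 to 0.94 for macrophage, 0.00933 to 0.698 for erythroid, 0.251 to 0.958 for megakaryocyte, 0.498 to 0.928 for T and NK, 0.218 to 0.931 for dendritic and 0.219 to 0.905 for mast cell markers. Over the reported genes and settings compared 3164 values kept their direction and side of the threshold, 23 reversed, 16 lost and 25 gained a call; for lists these were 429, 39, 55 and 17. The simulated test, with 3 libraries per group, recovered 20% of genes changed 1.5-fold. Smaller changes of single genes were thus mostly not detectable. In the real libraries the share may be lower, since fewer genes passed there than in the simulation.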

Other observations

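The window scan and its explanation were tested after the result was seen. Groups of genes with p under 0.01 also lay on chromosomes other than 1. In windows of 20 Mb, 18 of 501 passed an adjusted p of 0.05, and 10 of them lay outside chromosome 1. The window test treats neighbouring genes as independent, so its p-values may be too small. Windows started every 5 Mb and so overlapped: the 10 make up 3 regions, on chromosome 5 from 100 to 125 Mb, on chromosome 8 from 15 to 60 Mb and on chromosome 13 from 105 to 130 Mb. From 30 to 50 Mb on chromosome 8, 10 of 73 genes had p under 0.01 (adjusted p = 1.98e-07), with Fut10 and Dctd among those higher and Ppp2cb, Lonrf1, Mtus1 and Snx25 among those lower. On chromosome 5 between 105 and 125 Mb there were 9 of 241 genes (adjusted p = 0.00709), among them Pebp1 and Rplp0 with higher and Prkab1 and Setd8 with lower values. A hypothesis is that stretches of DNA from another strain elsewhere in the genome differ between the libraries. The 10 overlapping windows bear on it only weakly: of the 10 splits of the libraries 2 gave as many windows outside chromosome 1, and another split, wild-type replicates 1 and 3 with mutant replicate 2 against the rest, gave 13. Stretches still segregating among the animals would show in such splits too, so this stays open. These genes were named after their values were seen.

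Over the 10 splits, 2 gave at least 1 gene higher or lower, as many as the 1 higher gene of the real split, with 1 as the highest other. For the 2 lower genes only the real split, 1 of 10, gave as many, the highest other being 1. As many gene lists past the threshold as the real 10 came from 3 of 10 splits, with 14 as the highest other. DESeq2 called 44 genes in the real split, 4 of 10 splits gave as many, and the highest other was 197. That split set wild-type replicates 1 and 2 and mutant replicate 3 against the rest. In it edgeR called 0 genes, and what sets it apart was not tested. With 10 splits no share can fall under 0.05.

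The cAMP/CREB response genes, at a camera adjusted p of 0.133 as reported, had 0.0251 with the presence of Y-linked reads as a covariate and 0.0102 without the 2 libraries that hold them, but an adjusted p of 0.857 with an estimated correlation. The gain was not particular to this list: B and plasma cell markers had 0.00505 and 0.00133 in the same settings, and without the 2 libraries erythroid markers had 0.0335 and macrophage markers 0.00479. Without them the long-term HSC signature (0.531) and S phase genes (0.672) lost their calls. Over all alternatives run the cAMP/CREB list ran from 0.00718 to 0.858.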
